A study of Homo sapiens and Mus musculus with 99 samples.

How the data were processed

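The authors deposited 13 tables of gene counts, 7 from mouse and 6 from human cells, with 99 count columns, of which 0 were left unused. Per the labels, RNA was taken with a TIANGEN RNAprep kit and libraries were made with the NEBNext Ultra RNA kit for Illumina, which does not mark the strand. Per the submitters' processing notes, reads were aligned to hg19 or mm10 with HISAT2 2.2.1 and SAMtools, fragments per gene were counted with featureCounts 2.0.2, and genes were tested with DESeq2 1.36.0 in R 4.2.2. How the strand was set in counting is not given in the sources used here. The submitters' own test results were not used here.

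The counts were used as deposited. In 3 pairs of columns (6 columns, IL33KO2 Lysenin, IL33KO2 PlyA2EryB and Rag2gc DPBS) both columns carried the same name, so they entered as 2 libraries without numbers. The BAPTA-AM columns of H292-2 name the chelator without Aeg-S/L. They were matched to the samples labelled Aeg-S/L+BAPTA-AM, the only BAPTA-AM samples the labels give for that table. The name of the deposited table gives ALT, whereas the labels of its samples give Aeg-S/L. Among pairs of libraries of a group, a chi-square per degree of freedom between the count columns was at least 2.95 in mouse (27 pairs, median 15.51) and 4.02 in human cells (30 pairs, median 16.12), so no library was a copy of another. The Lung4 table held 2 lines without a gene ID, with 3.0e-06% of its counts, and these were left out. Of 57820 human gene IDs, 51996 matched a name in the reference used here, and of 55401 mouse IDs 0 did. Mouse gene lists, cell type markers and the targeted genes Il33, Rag2 and Il2rg were therefore not analysed here.

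Each experiment was fitted on its own with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr over the groups, libraries scaled by TMM, and 1 coefficient per group tested by the quasi-likelihood F test, with p adjusted by Benjamini-Hochberg over the genes of a comparison. A gene was called at an adjusted p under 0.05. Standard errors were taken as the absolute log2 change divided by the square root of F. Differences between experiments were tested in joint fits, each effect taken against its own DPBS. For a gene with 0 counts in a group, the fold is given as at least the mean of the other group over a floor of 3 counts spread over the group. A median with bounds puts these floors in place of the fitted values.

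The response sets hold at most 200 genes, those with the smallest p among genes called with a log2 increase of at least 1 in one experiment, and were tested in other experiments only. Sets and lists were tested with camera (limma 3.58.1), with a preset correlation of 0.01 between genes and again with an estimated correlation. The adjusted p given for a set or list is the one with the estimated correlation, adjusted over all set tests, or over the lists of a comparison. Human lists with at least 3 tested members were used: immediate early genes, ERK feedback and output genes, EGF receptor ligands, epithelial cytokines, chemokines (14 of 15 names matched, CCL5 without an ID), NF-kB feedback genes, targets of calcium, CREB and NFAT, integrated stress response, ER chaperones, heat shock genes, NRF2 targets, interferon-stimulated genes, cholesterol synthesis, annexins and membrane repair, cell cycle, and mucus and goblet genes. Named genes are list members, or lie among the 15 largest increases or 10 largest decreases called in a comparison with at least 1 CPM in the higher group and no overlap between replicates. For mouse, the IDs that met this rule in the most comparisons are given. The values of 1 list member are not reported here.

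The comparisons, lists, sets, naming rule and alternatives were written down before the data were examined. Tests of the Lung4 proteins against each other and fits without libraries that stand apart were added after. Which gene values to recompute under the alternatives was also settled after the values were seen. Counts of called genes and values of named genes were recomputed with DESeq2 1.42.0, without the low-count filter, with DESeq2 size factors, with the replicate number as a block where the columns carry numbers, and without each library of the compared groups in turn. Where this left a group with a single library, that library was assumed to vary like those of the other groups of the fit. The 12 shifts of response sets with inhibitors, chelators and knockout extracts against the stimulus were recomputed with DESeq2 size factors, with the block, with smaller sets, with an estimated correlation and without each library of the compared groups in turn.

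A self-test changed 100 genes by a log2 of 1 and 100 by 2 in simulated counts. For H1437-1 ALT, 26% and 94% were recovered, with 7 false among 127 calls over 15913 genes. For H1437-3 Aeg-S/L, 91% and 98% were recovered, with 23 false among 212 calls over 16434 genes. For Lung2 Aeg-S/L, 44% and 91% were recovered, with 6 false among 141 calls over 18411 genes. The share of false calls lay above 0.05 for H1437-3 and slightly above it for H1437-1. Far more genes were called in many real comparisons than were changed here, so these rates need not hold for them.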

Results

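The data were gene counts from RNA sequencing of 99 libraries in 13 experiments. Of these, 48 libraries in 23 groups came from mouse lung epithelial cells, isolated 6 h after intranasal treatment. The other 51 libraries in 24 groups came from NCI-H1437 and NCI-H292, epithelial lines from non-small cell lung cancers, collected 4 h after treatment. The stimuli were ALT, an extract of the fungus *Alternaria alternata*; the proteins Aeg-S and Aeg-L, alone or together (Aeg-S/L); extracts labelled aegs KO and aegl KO; and the pore-forming proteins lysenin (from earthworms), PlyA2EryB and LSL. Each was set against the mock treatment of its own experiment, DPBS. The mouse experiments are called Lung1 to Lung4, IL33KO1 and IL33KO2 (IL-33 knockout mice) and Rag2gc (mice lacking Rag2 and the common gamma chain), and the human ones H1437-1 to H1437-4, H292-1 and H292-2. Groups held 2 libraries each, except in Lung1 and H1437-1, where they held 3. Libraries held 29.6 to 66.3 M counted fragments in mouse and 32.4 to 53.2 M in human cells. Changes are given on a log2 scale ± standard error with edgeR's adjusted p, and levels as mean ± standard deviation in CPM, counts scaled to library size.

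The extract and the joined proteins were first compared with DPBS in mouse lung. This asks what each does to lung epithelial cells and whether Aeg-S and Aeg-L act alone. The mix of cells in the mouse libraries was not checked, since cell type markers were not analysed. Mouse genes are given by Ensembl ID, since their names are not given in the sources used here. Those shown were picked for lying among the largest changes most often over 12 comparisons. Their recurrence between experiments follows from that choice and is no independent support. ENSMUSG00000028940.2 (mm10, 4:152158867–152162469) fell by 6.47 ± 0.28 under ALT in Lung1 (adjusted p = 2.956e-09), from 26.1 ± 5.24 to 0.294 ± 0.155 CPM. Under Aeg-S/L in Lung2 it fell by 4.17 ± 0.46 (adjusted p = 0.0004434). ENSMUSG00000024598.9 fell by 2.17 ± 0.34 (adjusted p = 0.0001256) and by 2.84 ± 0.52 (adjusted p = 0.003788) in the same order. ENSMUSG00000026420.16 (1:130882074–130887454) had 0 counts in DPBS of Lung2 and 18.3 ± 2.05 CPM under Aeg-S/L, at least 424-fold higher (adjusted p = 0.0001248). In Lung1 it stood at 3.58 ± 0.640 CPM under ALT against 0.0206 ± 0.0356 CPM. Among 17801 genes tested in Lung1, 5080 rose and 5353 fell under ALT, 2282 and 2173 of them at least 2-fold. Among 19053 in Lung2, 3642 rose and 3754 fell under Aeg-S/L, 2200 and 1978 of them at least 2-fold. The Lung2 total of 7396 became 4246 without Aeg-S/L 1, 4390 without Aeg-S/L 2 and 4876 without DPBS 1.

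The same genes answered to the extract and to Aeg-S/L. Of 200 genes that rose under ALT in Lung1 (the ALT set), 199 rose under Aeg-S/L in Lung2, with a median change of 2.66 (quartiles 1.98 and 3.78, adjusted p = 0.0002145 with an estimated correlation between genes). Of 200 genes that rose under Aeg-S/L (the Aeg-S/L set), 195 rose under ALT in Lung1, median 2.28 (1.61 and 3.2, adjusted p = 0.002264). Under Aeg-S alone the ALT set had a median of 0.06 (−0.21 and 0.35, adjusted p = 0.1395), and under Aeg-L alone 0.13 (−0.04 and 0.29, adjusted p = 0.04852), with 0 of 200 genes passing in either. Over all genes edgeR called 0 for Aeg-S and 0 for Aeg-L. At an unadjusted p under 0.05 there were 1178 and 599, and DESeq2 called 13 and 10. Without the low-count filter edgeR called 775 and 132. The Aeg-S count became 1329 without Aeg-S 1, with Aeg-S 2 alone in its group, and the Aeg-L count 1 without Aeg-S 2, a library that stands apart. A test of the Aeg-S/L change against the sum of the changes under Aeg-S and Aeg-L found 2117 genes above the sum and 2142 below it. That total of 4259 became 1897 without Aeg-S/L 1, 1908 without Aeg-S/L 2, 2231 without DPBS 2, 2026 without Aeg-L 1 and 2465 without Aeg-L 2.

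**Figure D1:**
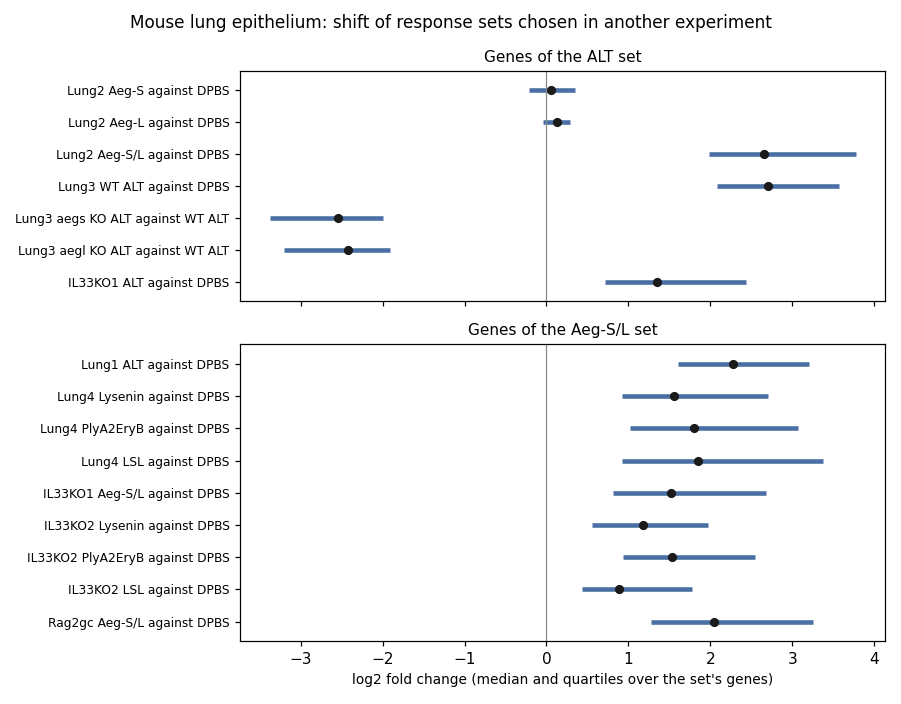
Median (point) and quartiles (bar) of the log2 fold change in mouse lung over the genes of the ALT set (upper panel) and the Aeg-S/L set (lower panel), for comparisons outside the experiment each set was chosen in. Under Aeg-S and Aeg-L alone the medians lay at 0.06 and 0.13, and under Aeg-S/L at 2.66; with the aegs KO and aegl KO extracts set against the WT extract they lay at −2.55 and −2.42.

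Extracts labelled aegs KO and aegl KO were set against the extract labelled WT in Lung3, to see how much of the response is lost with either. ENSMUSG00000028940.2 fell by 5.34 ± 0.38 under the WT extract (adjusted p = 6.318e-05), and stood 5.16 ± 0.37 higher with the aegs KO than with the WT extract and 4.63 ± 0.37 higher with the aegl KO extract. ENSMUSG00000026420.16 rose by 5.78 ± 0.76 under the WT extract (adjusted p = 0.0008412), to 4.78 CPM from 0.0843. With the knockout extracts it stood at 0.0147 and 0.0140 CPM. The ALT set rose by a median of 2.7 under the WT extract (2.08 and 3.57, 200 of 200 genes, adjusted p = 0.0001833). Against the WT extract, 200 of 200 were lower with aegs KO, median −2.55 (−3.38 and −1.99, adjusted p = 0.000161 with an estimated correlation), and 200 of 200 with aegl KO, median −2.42 (−3.2 and −1.91, adjusted p = 0.0001271). Against DPBS the set moved little, by 0.19 with aegs KO (adjusted p = 0.04525) and 0.26 with aegl KO (adjusted p = 0.01011), with 0 genes passing.

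Over all 19092 genes of Lung3, 2956 rose and 3583 fell under the WT extract. That total of 6539 became 3228 without WT ALT 1, 3323 without WT ALT 2 and 10266 without DPBS 1. Against the WT extract, 2992 genes were higher and 2515 lower with aegs KO. That total of 5507 became 2548 without WT ALT 1, 2648 without WT ALT 2, 2297 without aegs KO 1 and 2532 without aegs KO 2. With aegl KO 2899 were higher and 2416 lower, and the total of 5315 became 2316 without WT ALT 1, 2396 without WT ALT 2, 2209 without aegl KO 1 and 2303 without aegl KO 2. Without DPBS 2, which stands apart, the totals were 9265 and 9071. The medians of the ALT set moved far less, to between −2.57 and −2.49 for aegs KO and between −2.49 and −2.38 for aegl KO.

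Lung4, the experiment labelled wild type, asked whether pore-forming proteins from other sources move the same genes. ENSMUSG00000026420.16 rose by 5.82 ± 0.34 under lysenin (adjusted p = 2.284e-11), 6.46 ± 0.32 under PlyA2EryB (adjusted p = 1.745e-12) and 6.13 ± 0.33 under LSL (adjusted p = 5.652e-12). ENSMUSG00000013936.12 (5:122100951–122113472), with 0 counts in DPBS, reached 4.22 ± 0.700, 6.14 ± 0.187 and 3.50 ± 0.0317 CPM, at least 134-fold, 195-fold and 111-fold higher. It lay among the largest increases in 7 of the 12 mouse comparisons, and its values under ALT and Aeg-S/L are not reported here. Its rise therefore does not show that the same genes moved. ENSMUSG00000028940.2 fell by 4.2 ± 0.12, 4.89 ± 0.13 and 2.81 ± 0.11. The Aeg-S/L set, with 199 genes tested, rose under all 3 proteins: 188 genes with a median of 1.56 under lysenin (0.92 and 2.7, adjusted p = 0.0002792 with an estimated correlation), 192 with 1.8 under PlyA2EryB (1.02 and 3.07, adjusted p = 6.311e-05) and 193 with 1.85 under LSL (0.92 and 3.37, adjusted p = 0.0002065). Of 18752 genes, 6010 rose and 5924 fell under lysenin, 6142 and 5989 under PlyA2EryB, and 6206 and 6133 under LSL.

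Tests of the proteins against each other in Lung4 were chosen after the values were seen. ENSMUSG00000028940.2 was higher under LSL than under lysenin by 1.39 ± 0.14 (adjusted p = 4.404e-07) and than under PlyA2EryB by 2.08 ± 0.15 (adjusted p = 8.611e-09), and lower under PlyA2EryB than under lysenin by 0.69 ± 0.17 (adjusted p = 0.007256). Between PlyA2EryB and lysenin 2189 genes were higher and 2063 lower, but only 173 and 94 by at least 2-fold. Between LSL and lysenin 2592 were higher and 2413 lower, 437 and 116 by at least 2-fold, and between LSL and PlyA2EryB 2993 and 3273, 464 and 234 by at least 2-fold. The first total, 4252, became 2332 without Lysenin 1, 2646 without Lysenin 2, 2484 without PlyA2EryB 1 and 2642 without PlyA2EryB 2. The second, 5005, became 3220 without Lysenin 2, 3209 without LSL 1 and 3160 without LSL 2, and the third, 6266, became 4135 without LSL 1. Doses are not given in the sources used here.

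Mice without IL-33, and mice without Rag2 and the common gamma chain, were treated to see which changes remain in their absence. In Rag2gc, ENSMUSG00000026420.16 went from 0 counts to 8.43 ± 0.363 CPM under Aeg-S/L, at least 308-fold higher (adjusted p = 4.199e-08), and ENSMUSG00000028940.2 fell by 5.07 ± 0.11 (adjusted p = 4.521e-10). In IL33KO1 the former rose at least 208-fold under Aeg-S/L (adjusted p = 0.009014) and at least 155-fold under ALT (adjusted p = 0.01607). The latter fell by 3.73 ± 0.62 under Aeg-S/L (adjusted p = 0.023), while its change under ALT, −1.94 ± 0.57, did not pass (adjusted p = 0.1143). The Aeg-S/L set rose in Rag2gc by a median of 2.04 (1.27 and 3.25, 188 of 198 genes, adjusted p = 0.008532 with an estimated correlation) and in IL33KO1 by 1.52 (0.81 and 2.68, 122 of 199, adjusted p = 0.008924). The ALT set rose in IL33KO1 under ALT by 1.35, or 1.32 with bounds for genes with 0 counts in a group (0.71 and 2.44, 73 of 197, adjusted p = 0.01937).

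In IL33KO2 the Aeg-S/L set rose by 1.18 under lysenin (0.56 and 1.97, 168 of 199 genes, adjusted p = 8.294e-05), 1.53 under PlyA2EryB (0.93 and 2.54, 176, adjusted p = 6.311e-05) and 0.89 under LSL (0.43 and 1.78, 152, adjusted p = 0.0001151). ENSMUSG00000013936.12 went from 0 counts to at least 128-fold, 193-fold and 137-fold higher. Over all genes, 3895 rose and 3555 fell under lysenin, 4826 and 4626 under PlyA2EryB, 3668 and 3360 under LSL, and 6066 and 6187 under Aeg-S/L in Rag2gc. The lysenin total of 7450 became 11604 without DPBS 2 and 4206 or 4326 without either Lysenin library. The PlyA2EryB total of 9452 became 6293 without one PlyA2EryB library. The LSL total of 7028 became 11510 without DPBS 2, 3526 without LSL 1 and 3783 without LSL 2. In IL33KO1, 436 genes rose and 94 fell under ALT, and 1163 and 822 under Aeg-S/L. The ALT total of 530 became 2076 without DPBS 1, 2820 without DPBS 2, 25 without ALT 1 and 325 without ALT 2. DPBS 1 stands apart, with 5.83% of counts on mitochondrial genes against 3.06% in DPBS 2. The total was 2465 with DESeq2, 2803 without the low-count filter and 266 with the replicate number as a block. The Aeg-S/L total of 1985 became 6204 without DPBS 2 and 222 without either Aeg-S/L library, and 4300, 4648 and 1074 in the same 3 settings. No experiment held mice with and without the knockout, so genotype cannot be told apart from experiment.

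In both human lines the extract and Aeg-S/L raised immediate early genes, chemokines and cytokines. The immediate early transcription factor FOS (ENSG00000170345.5, hg19 14:75745477–75748933) rose by 6.41 ± 0.5 (adjusted p = 6.906e-05) and 7.2 ± 0.16 (adjusted p = 9.268e-15) under ALT in H1437-1 and H1437-4, and by 8.39 ± 0.33 (adjusted p = 1.785e-08) and 8.4 ± 0.27 (adjusted p = 6.354e-13) under Aeg-S/L in H1437-2 and H1437-3. In NCI-H292 it rose by 9.25 ± 0.2 under ALT (adjusted p = 1.757e-09) and 9 ± 0.14 under Aeg-S/L (adjusted p = 7.084e-20). The neutrophil attractant CXCL8 (ENSG00000169429.6, 4:74606223–74609433) rose by 7.65 ± 0.78, 8.62 ± 0.2, 8.11 ± 0.32 and 8.48 ± 0.27 in H1437-1, H1437-4, H1437-2 and H1437-3, and by 7.15 ± 0.24 and 8.79 ± 0.18 in H292-1 and H292-2. The cytokine IL6 (ENSG00000136244.7, 7:22765503–22771621) had 0 counts in DPBS of all 4 NCI-H1437 experiments. It reached 29.3 ± 12.1 CPM in H1437-1, at least 1090-fold higher (adjusted p = 0.00308), 110 ± 27.6 CPM in H1437-4 (at least 3231-fold), 94.0 ± 0.659 CPM in H1437-2 (at least 2341-fold) and 125 ± 0.538 CPM in H1437-3 (at least 2882-fold). In H292-1 and H292-2 IL6 rose by 7.69 ± 0.35 and 7.33 ± 0.19. The alarmin IL33 did not pass in H1437-1 (−1.82 ± 0.6, adjusted p = 0.1291), H1437-4 (−0.11 ± 0.75), H1437-2 (−0.18 ± 0.81), H1437-3 (−0.96 ± 0.89) or H292-1 (0.37 ± 0.34, adjusted p = 0.4771). Its rise of 0.76 ± 0.27 in H292-2 (adjusted p = 0.02656) did not pass without Aeg-S/L 1 (adjusted p = 0.1401), Aeg-S/L 2 (adjusted p = 0.05447) or DPBS 2 (adjusted p = 0.234).

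By list, 19 of 20 immediate early genes rose in each of the 4 NCI-H1437 experiments, with medians of 3.36 (H1437-1), 3.72 (H1437-4), 4.3 (H1437-2) and 4.58 (H1437-3), and EGR1 rose by 6.66 ± 0.47, 7.13 ± 0.19, 8.18 ± 0.33 and 8.26 ± 0.31. In H292-1 18 rose and 1 fell (median 4.15) and in H292-2 19 rose and 1 fell (median 4.96). The gene that fell was JUNB, by 0.81 ± 0.15 (adjusted p = 0.003193) and 0.39 ± 0.07 (adjusted p = 0.000145), whereas it rose by 2.48 ± 0.08 in H1437-4, 2.62 ± 0.34 in H1437-2 and 2.07 ± 0.09 in H1437-3. In H1437-1 JUNB rose by 2.06 ± 0.37 (adjusted p = 0.008551), not passing without DPBS 2 (adjusted p = 0.05153). MYC rose by 2.41 ± 0.16 in H292-1 and 2.36 ± 0.11 in H292-2, and did not pass in NCI-H1437, where it changed by 0.23, 0.08, 0.23 and 0.1. Chemokines rose as a list wherever the estimated correlation left the call in place: 7 of 8 in H1437-4 (median 6.51), 5 of 7 in H1437-2 (7.89, 6 adjusted over the list alone), 6 of 9 in H1437-3 (6.73, 7 adjusted over the list alone), 5 of 9 in H292-1 (5.38, 8 adjusted over the list alone) and 8 of 9 in H292-2 (6.43). Epithelial cytokines rose in the same 5 experiments: 8 of 10 (median 2.85), 5 of 9 (1.81, 7 adjusted over the list alone), 9 of 11 (2.07), 7 of 12 (1.38) and 12 of 13 (2.76). The pyrogenic cytokine IL1A rose by 5.62 ± 0.43, 5.73 ± 0.52, 6.9 ± 0.27, 4.2 ± 0.17 and 4.9 ± 0.07. In H1437-1 it rose by 2.67 ± 0.49 (adjusted p = 0.01036), not passing without ALT 2 (adjusted p = 0.0633), ALT 3 (adjusted p = 0.05607) or DPBS 2 (adjusted p = 0.05071). In H1437-1, 5 of 7 chemokines and 5 of 9 cytokines rose (7 cytokines, with 1 lower, adjusted over the list alone), but the lists gave adjusted p = 0.09068 and adjusted p = 0.0771 with an estimated correlation.

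Feedback genes of 2 signalling routes rose as well. Among 13 NF-kB feedback genes, 10 rose in H1437-1 (12 adjusted over the list alone, median 2.07, adjusted p = 0.01281 with an estimated correlation), 13 in H1437-4 (1.95, adjusted p = 0.002912), 12 in H1437-2 (13 adjusted over the list alone, 2.09, adjusted p = 0.0001657), 13 in H1437-3 (2.23, adjusted p = 0.0009896), 10 in H292-1 (11 adjusted over the list alone, 1.28, adjusted p = 0.009269) and 12 in H292-2 (1.49, adjusted p = 0.0009978). TNFAIP3, which ends NF-kB signalling, rose by 6.3 ± 0.56, 6.67 ± 0.2, 7.08 ± 0.33, 7.94 ± 0.15, 5.59 ± 0.15 and 6.35 ± 0.08. Among 13 ERK feedback and output genes, 8 rose in H1437-1 (9 adjusted over the list alone, median 1.13, adjusted p = 0.005936), 8 in H1437-4 (9, 0.59, adjusted p = 0.01546), 6 in H1437-2 (9, 0.79, adjusted p = 0.009681), 11 in H1437-3 (0.79, adjusted p = 0.001505), 12 in H292-1 (1.06, adjusted p = 0.009269) and 12 in H292-2 (1.47, adjusted p = 0.002034). The ERK phosphatase DUSP6 (ENSG00000139318.7, 12:89741009–89747048) rose by 1.98 ± 0.09, 2.52 ± 0.25 and 2.4 ± 0.08 in the last 3 NCI-H1437 experiments and by 5.19 ± 0.16 and 5.02 ± 0.12 in NCI-H292. In H1437-1 its change of 1.13 ± 0.32 did not pass with edgeR (adjusted p = 0.07357) but passed with DESeq2 (adjusted p = 0.006437). Targets of calcium, CREB and NFAT, which share NR4A1, NR4A2 and NR4A3 with the immediate early list, rose in all 6: 8 of 10 (median 2.05), 9 of 10 (2.42), 9 of 10 (2.99), 10 of 10 (3.05), 9 of 11 (2.3) and, with 1 lower, 9 of 10 (2.25). Among them PTGS2, which makes prostaglandins, rose by 3.71 ± 0.39, 5.46 ± 0.13, 5.47 ± 0.25, 5.46 ± 0.14, 6.39 ± 0.18 and 6.91 ± 0.1.

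Genes also fell. The pro-apoptotic gene BMF (ENSG00000104081.9, 15:40380091–40401093) fell by 4.58 ± 0.26 in H1437-1 (adjusted p = 2.159e-05), 2.81 ± 0.22 in H1437-4, 3.06 ± 0.32 in H1437-2, 3.23 ± 0.43 in H1437-3, 4.19 ± 0.27 in H292-1 (adjusted p = 3.269e-06) and 3.54 ± 0.16 in H292-2 (adjusted p = 7.76e-13). HMOX1 (ENSG00000100292.12, 22:35776354–35790207), which breaks down heme, fell by 5.03 ± 0.22 in H292-1, from 81.0 ± 8.43 to 2.48 ± 0.717 CPM (adjusted p = 1.369e-07), and by 4.76 ± 0.13 in H292-2 (adjusted p = 1.992e-16). In H1437-4 and H1437-3 it fell by 0.92 ± 0.06 (adjusted p = 4.934e-09) and 0.52 ± 0.05 (adjusted p = 1.658e-06). Its change of −0.36 ± 0.23 in H1437-2 did not pass (adjusted p = 0.3575). Its fall of 0.97 ± 0.22 in H1437-1 (adjusted p = 0.02809) did not pass without ALT 1 (adjusted p = 0.101), ALT 2 (adjusted p = 0.1578), ALT 3 (adjusted p = 0.135) or DPBS 2 (adjusted p = 0.06253). HMOX1 belongs to the NRF2 targets, of which 8 of 9 fell in H292-1 (median −1.25, adjusted p = 0.005219 with an estimated correlation), 9 of 9 in H292-2 (−1.32, adjusted p = 0.001713) and 6 of 9 in H1437-3 (−0.49, adjusted p = 0.04546). In H1437-4 5 fell and 1 rose (−0.22, adjusted p = 0.5764 with an estimated correlation). The list did not pass in H1437-1 (1 of 9 lower, −0.05, adjusted p = 0.4596, 2 with 1 higher adjusted over the list alone) or H1437-2 (1 of 9 lower, −0.31, adjusted p = 0.2358, 3 adjusted over the list alone). Over all genes, ALT raised 583 and lowered 183 of 16251 in H1437-1, 2632 and 2851 of 16711 in H1437-4, and 1924 and 1874 of 16613 in H292-1, while Aeg-S/L raised 615 and lowered 525 of 16962 in H1437-2, 2596 and 2670 of 16904 in H1437-3, and 3628 and 3453 of 16380 in H292-2. The H1437-1 total of 766 became 373 without ALT 1, 294 without ALT 2, 299 without ALT 3 and 410 without DPBS 2, but 1394 with DESeq2, 1153 without the low-count filter and 2812 without DPBS 1 and ALT+Tra 3, which stand apart. The H1437-2 total of 1140 became 269 without Aeg-S/L 1, 337 without Aeg-S/L 2, 337 without DPBS 1 and 270 without DPBS 2, but 1931 with DESeq2, 2143 without the filter and 1881 without Aeg-S 2, which stands apart. The H292-1 total of 3798 became 1530 without DPBS 1, 2519 without DPBS 2, 1481 without WT ALT 1 and 1520 without WT ALT 2.

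Aeg-S and Aeg-L alone were tested in H1437-2. FOS changed by 0.04 ± 0.25 under Aeg-S (adjusted p = 0.9544) and 0.25 ± 0.25 under Aeg-L (adjusted p = 1), and CXCL8 by 0.68 ± 0.25 (adjusted p = 0.5281) and −0.02 ± 0.25 (adjusted p = 1). The Aeg-S/L set chosen in H1437-3 had a median of −0.04 under Aeg-S (−0.32 and 0.24, adjusted p = 0.8743) and 0.06 under Aeg-L (−0.05 and 0.19, adjusted p = 0.2676), against 2.29 under Aeg-S/L (1.5 and 3.28, 193 of 200 genes, adjusted p = 6.311e-05 with an estimated correlation). Over all genes edgeR called 0 for each protein. At an unadjusted p under 0.05 there were 1491 for Aeg-S and 186 for Aeg-L, and DESeq2 called 3 and 0. Without the low-count filter edgeR called 278 and 9. The Aeg-S count became 1 without DPBS 2 and 1544 without Aeg-S 1, which leaves Aeg-S 2 alone, a library that stands apart, with the spread taken from the other groups, and the Aeg-L count became 1 without Aeg-L 1, Aeg-L 2 or DPBS 2. Set against the sum of the single changes, Aeg-S/L gave more than the sum for 18 of 20 immediate early genes (median 4.57, adjusted p = 0.0003601), 5 of 7 chemokines (6.45, adjusted p = 0.001314) and 11 of 13 NF-kB feedback genes (12 adjusted over the list alone, 2.25, adjusted p = 0.0003601). Over all genes 282 lay above the sum and 147 below it. That total of 429 became 270 without Aeg-L 1, 4373 without Aeg-L 2, 3002 without Aeg-S 1, 283 without Aeg-S 2, 148 without Aeg-S/L 1, 163 without Aeg-S/L 2, 159 without DPBS 1 and 180 without DPBS 2, and 1420 with DESeq2 and 1913 without the filter.

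The sets chosen in one human experiment rose in the others. The ALT set of H1437-4 rose in H1437-1 by 1.91 (1.27 and 2.8, 165 of 200 genes, adjusted p = 0.000935 with an estimated correlation). The ALT set of H1437-1 rose in H1437-4 by 1.87 (1.03 and 3.1, 187 of 200, adjusted p = 0.0002249) and in H292-1 by 0.98 (0.11 and 2.73, 114 of 185, with 11 lower, adjusted p = 0.0001403). The Aeg-S/L set of H1437-2 rose in H1437-3 by 2.47 (1.68 and 3.6, 200 of 200, adjusted p = 0.0002145) and in H292-2 by 2.22 (1.27 and 3.9, 184 of 198, with 6 lower, adjusted p = 0.000161).

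**Figure D2:**
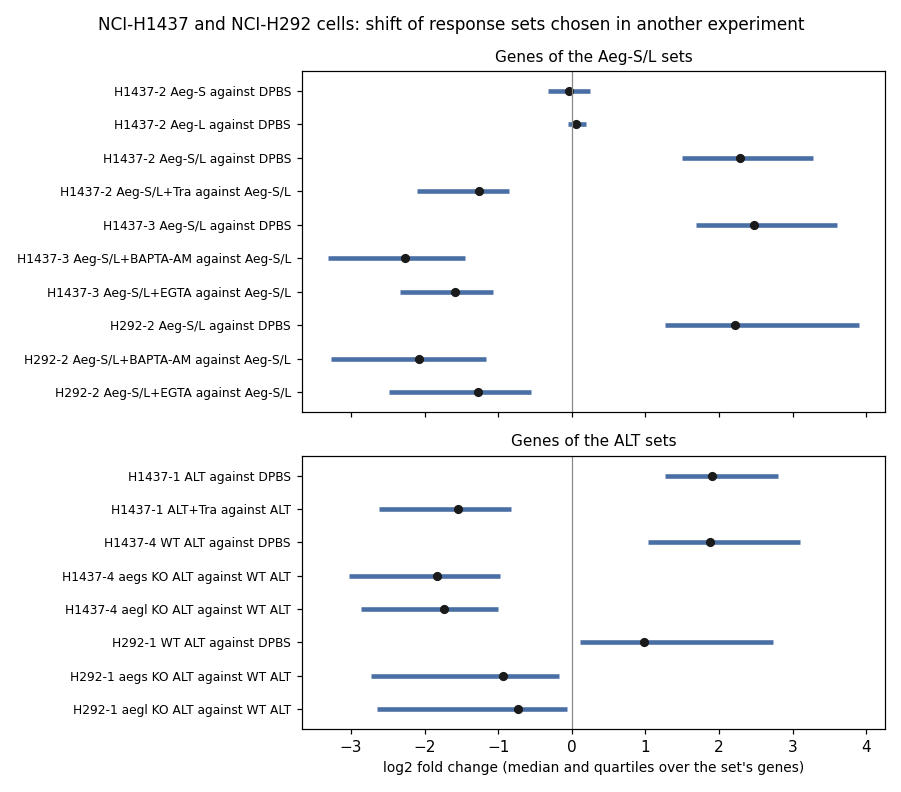
Median (point) and quartiles (bar) of the log2 fold change over the genes of the Aeg-S/L sets (upper panel) and ALT sets (lower panel) in NCI-H1437 and NCI-H292 cells, each set chosen in another experiment. Bars to the left of 0 stand for inhibitor, chelator or knockout extract against the stimulus alone, such as −2.26 for BAPTA-AM and −1.59 for EGTA in H1437-3.

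The MEK inhibitor labelled Tra was added to ALT in H1437-1 and to Aeg-S/L in H1437-2, to see which changes need MEK. With it, EGR1 fell by 9.57 ± 0.54 (adjusted p = 7.839e-06) and 7.72 ± 0.32 (adjusted p = 1.925e-07) against the stimulus alone, and DUSP6 fell by 5.82 ± 0.4, from 30.0 ± 1.98 to 0.516 ± 0.281 CPM (adjusted p = 2.502e-05), and by 3.52 ± 0.26 (adjusted p = 1.523e-05). SPRY4, an inhibitor of the same pathway, fell by 6.22 ± 0.41 (adjusted p = 1.999e-05) and 2.49 ± 0.19 (adjusted p = 1.778e-05). FOS fell by 5.04 ± 0.47 (adjusted p = 0.0001861) and 4.23 ± 0.27 (adjusted p = 4.868e-06), and CXCL8 by 5.23 ± 0.69 (adjusted p = 0.001699) and 4.61 ± 0.27 (adjusted p = 2.912e-06). IL6 fell by 4.53 ± 0.43 in H1437-2 (adjusted p = 0.0002866) and by 4.77 ± 0.91 in H1437-1 (adjusted p = 0.01976), the latter not passing without ALT 2 (adjusted p = 0.07589), ALT 3 (adjusted p = 0.07818) or ALT+Tra 2 (adjusted p = 0.1109). BMF rose by 4.5 ± 0.26 (adjusted p = 7.839e-06) and 3.18 ± 0.32 (adjusted p = 0.0001741). Immediate early genes fell in both, 17 of 20 in H1437-1 (18 adjusted over the list alone, median −3, adjusted p = 0.007969) and 19 of 20 in H1437-2 (20 adjusted over the list alone, −2.36, adjusted p = 0.0004258). ERK feedback and output genes fell in both, 10 of 13 (11, with 1 higher, adjusted over the list alone, −1.92, adjusted p = 0.002214) and 7 of 13 (10 adjusted over the list alone, −1.06, adjusted p = 0.000667). NF-kB feedback genes fell in H1437-2, 9 of 13 (11 adjusted over the list alone, −1.66, adjusted p = 0.0002121). In H1437-1 6 of 13 fell (9 adjusted over the list alone, −1.14), and the list had adjusted p = 0.08705 with an estimated correlation.

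Under Tra part of the response remained and part went below the level in DPBS. Against DPBS, FOS was still 4.15 ± 0.27 higher (adjusted p = 8.824e-06) and CXCL8 3.51 ± 0.26 higher (adjusted p = 2.023e-05) with Aeg-S/L and Tra in H1437-2, whereas in H1437-1 FOS (1.37, adjusted p = 0.2141) and CXCL8 (2.42, adjusted p = 0.1723) did not pass; CXCL8 passed there without ALT+Tra 3 (adjusted p = 0.009618). With DESeq2 both FOS (adjusted p = 0.03403) and CXCL8 (adjusted p = 0.001799) passed in H1437-1. DUSP6 lay below its DPBS level in H1437-1 by 4.69 ± 0.39 (adjusted p = 0.001299), but its change of −1 ± 0.24 in H1437-2 did not pass with edgeR (adjusted p = 0.1792) and passed with DESeq2 (adjusted p = 0.01225). ERK feedback and output genes lay below DPBS as a list in H1437-1, 3 of 13 (8, with 1 higher, adjusted over the list alone, median −0.96, adjusted p = 0.03194 with an estimated correlation). In H1437-2 1 of 13 was lower (2 adjusted over the list alone, −0.18, adjusted p = 0.273 with an estimated correlation). SPRY4 lay below DPBS in both, at −4.32 ± 0.39 in H1437-1 (adjusted p = 0.001299) and −1.17 ± 0.18 in H1437-2 (adjusted p = 0.01201). Immediate early genes (median 1.6, adjusted p = 0.001802), chemokines (4.13, adjusted p = 0.0005226) and NF-kB feedback genes (0.89, adjusted p = 0.0005226) stayed above DPBS as lists in H1437-2. These lists did not pass in H1437-1 (0.14, 2.4 and 0.77, adjusted p = 0.8995, 0.6389 and 0.2246). The response sets fell by a median of 1.54 against ALT (−2.62 and −0.82, 137 of 200 genes lower, adjusted p = 0.002366 with an estimated correlation) and by 1.26 against Aeg-S/L (−2.1 and −0.85, 131 of 200, adjusted p = 6.311e-05). Against DPBS they stood at 0.4 (−0.19 and 0.97, 13 of 200 higher, 5 lower, adjusted p = 0.2503) and 0.8 (0.4 and 1.42, 64 of 200 higher, 1 lower, adjusted p = 0.0001546). Over all genes 216 were higher and 610 lower in H1437-1, and 21 and 195 in H1437-2. The total of 826 became 350 without ALT 1, 278 without ALT 2, 279 without ALT 3 and 319 without ALT+Tra 2, but 1593 with DESeq2, 1864 without the low-count filter and 2773 without DPBS 1 and ALT+Tra 3, which stand apart. The total of 216 became 92 without Aeg-S/L 1, 98 without Aeg-S/L 2, 80 without Aeg-S/L+Tra 1 and 84 without Aeg-S/L+Tra 2, but 424 with DESeq2 and 447 without the filter. Tra was not given without a stimulus, so its effect on resting cells is not separated.

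Calcium chelators were added to Aeg-S/L in H1437-3 and H292-2, BAPTA-AM, which enters cells, and EGTA, which stays outside. The BAPTA-AM count columns of H292-2 name the chelator without Aeg-S/L, and the name of their table gives ALT. They were taken for the samples labelled with Aeg-S/L and BAPTA-AM, so the H292-2 values with BAPTA-AM rest on that match. FOS fell by 7.09 ± 0.25 with BAPTA-AM in H1437-3, from 2801 ± 59.0 to 20.5 ± 0.146 CPM (adjusted p = 2.19e-12), and by 3.91 ± 0.21 with EGTA (adjusted p = 9.868e-10). In H292-2 it fell by 7.74 ± 0.13 (adjusted p = 2.425e-19) and 7.18 ± 0.12 (adjusted p = 2.848e-18). IL6 fell by 6.94 ± 0.14 and 6.08 ± 0.13 in H1437-3 and by 4.72 ± 0.14 and 4.76 ± 0.15 in H292-2, and CXCL8 by 4.84 ± 0.22 and 3.99 ± 0.21, and by 6.16 ± 0.14 and 4.48 ± 0.12. Immediate early genes fell in all 4 comparisons: 20 of 20 with BAPTA-AM in H1437-3 (median −3.49, adjusted p = 0.01032), 19 of 20 with EGTA, where MYC rose by 1.16 ± 0.05 (−2.49, adjusted p = 0.01213), 20 of 20 with BAPTA-AM in H292-2 (−4.65, adjusted p = 0.003473) and 17 of 20, with 1 higher, with EGTA (−3.24, adjusted p = 0.003226). Calcium, CREB and NFAT targets fell too, 10 of 10 (−2.68), 9 of 10 with 1 higher (−1.71), 9 of 10 (−2.32) and 8 of 10 (−1.76). ERK feedback and output genes fell with BAPTA-AM in H1437-3, 10 of 13 (11 adjusted over the list alone, −0.92, adjusted p = 0.005672), and with EGTA in H1437-3, 8 with 2 higher (−0.51, adjusted p = 0.007476), and H292-2, 8 with 1 higher (−0.52, adjusted p = 0.02565). With BAPTA-AM in H292-2, 9 fell and 1 rose (10 lower adjusted over the list alone, −0.72), and the list had adjusted p = 0.1079 with an estimated correlation. DUSP6 fell by 1.44 ± 0.07 with BAPTA-AM and 1.61 ± 0.07 with EGTA in H1437-3, and by 1.17 ± 0.09 and 2.39 ± 0.1 in H292-2. Chemokines fell, 6 of 9 (−3.73), 6 of 9 with 1 higher (−3.99, 7 lower adjusted over the list alone), 8 of 9 (−4.25) and 8 of 9 (−2.97). The Aeg-S/L set of H1437-2 fell by a median of 2.26 with BAPTA-AM (−3.31 and −1.45, 194 of 200 genes, adjusted p = 0.0003632 with an estimated correlation) and 1.59 with EGTA (−2.34 and −1.07, 195, adjusted p = 0.000405) in H1437-3, and by 2.08 (−3.27 and −1.16, 183 of 198, adjusted p = 0.0001833) and 1.28 (−2.49 and −0.55, 162, adjusted p = 0.0002145) in H292-2.

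The 2 chelators were tested against each other; their doses are not given in the sources used here. FOS was lower with BAPTA-AM than with EGTA in H1437-3 by 3.18 (95% interval −3.65 to −2.72, adjusted p = 1.314e-08) and in H292-2 by 0.56 (−0.83 to −0.3, adjusted p = 0.001196). IL6 did not differ in H292-2 (0.03, −0.33 to 0.4, adjusted p = 0.8927), its sign turning without EGTA 2 (−0.04) or BAPTA-AM 2 (−0.34). In H1437-3 IL6 was lower by 0.86 (−1.29 to −0.44, adjusted p = 0.002986), which did not pass without EGTA 1 (adjusted p = 0.05035). DUSP6 was higher with BAPTA-AM than with EGTA in H292-2 by 1.22 (1.01 to 1.42, adjusted p = 6.422e-09) and did not pass in H1437-3 (0.17, 0.01 to 0.33, adjusted p = 0.08342). As a list the ERK feedback and output genes did not differ between the chelators in H1437-3 (median −0.29, adjusted p = 0.3648) or H292-2 (0.22, adjusted p = 0.3591). The ER stress genes HERPUD1 and DDIT3 went apart. With EGTA, HERPUD1 rose against Aeg-S/L by 2.02 ± 0.07 in H1437-3 (adjusted p = 3.002e-12) and 3.39 ± 0.07 in H292-2 (adjusted p = 2.394e-17), and DDIT3 rose by 0.88 ± 0.12 and 2.57 ± 0.13, whereas with BAPTA-AM DDIT3 fell by 3.25 ± 0.15 in H1437-3. Between the chelators HERPUD1 differed by −3.07 (−3.22 to −2.92) and −4.35 (−4.51 to −4.18). ER chaperones as a list rose with EGTA in H292-2, 11 of 11 (median 1.06, adjusted p = 0.006273), and were lower with BAPTA-AM than with EGTA there, 11 of 11 (−1.38, adjusted p = 0.01133). In H1437-3, 8 of 11 rose with EGTA (0.31), with adjusted p = 0.05485 with an estimated correlation, and 8 of 11 were lower with BAPTA-AM (−0.59), with adjusted p = 0.06078 with an estimated correlation. The share of counts on mitochondrial genes was 1.94 ± 0.16% under Aeg-S/L in H292-2, 0.2 ± 0.02% with BAPTA-AM and 1.23 ± 0.24% with EGTA, and in H1437-3 3.36 ± 0.13%, 0.98 ± 0.25% and 2.32 ± 0.04%.

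Over all genes of H1437-3, 1957 were higher and 2720 lower with BAPTA-AM and 2667 and 2505 with EGTA, the latter total of 5172 becoming 3399 without Aeg-S/L 2. In H292-2 2881 were higher and 3329 lower with BAPTA-AM, and 3800 and 3560 with EGTA. Between the chelators 2817 were higher and 3561 lower with BAPTA-AM in H1437-3, and 3589 and 4048 in H292-2, where the matrix protein gene CCN1 was higher by 1.77 (95% interval 1.61 to 1.93). In H1437-3 CCN1 was higher by 2.08 (1.9 to 2.27). By the labels neither chelator was given without Aeg-S/L, so their effects on resting cells are not separated.

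With a chelator some genes still differed from DPBS. No group was given a chelator alone, so a remainder of the response cannot be told apart from an effect of the chelator. HMOX1 lay 5.28 ± 0.13 below DPBS with BAPTA-AM in H292-2 (2.02 ± 0.219 against 78.5 ± 1.77 CPM, adjusted p = 4.16e-16) and 3.78 ± 0.12 below it with EGTA (adjusted p = 1.147e-14). Under Aeg-S/L alone it lay 4.76 ± 0.13 below. In H1437-3 it lay 0.41 ± 0.05 and 0.36 ± 0.05 below with BAPTA-AM and EGTA, and 0.52 ± 0.05 under Aeg-S/L alone. BMF lay 4.02 ± 0.46 below DPBS with BAPTA-AM in H1437-3 (adjusted p = 5.156e-06) and 4.67 ± 0.17 below it in H292-2 (adjusted p = 1.261e-13), where it fell against Aeg-S/L by 1.13 ± 0.21. In H1437-3 its change of −0.79 ± 0.55 against Aeg-S/L did not pass (adjusted p = 0.3294). EGTA raised BMF against Aeg-S/L by 2.99 ± 0.43 in H1437-3 and 2 ± 0.16 in H292-2 (adjusted p = 8.463e-09). This left it at −0.24 ± 0.36 from DPBS in H1437-3, which did not pass (adjusted p = 0.8096), but still 1.54 ± 0.14 below DPBS in H292-2 (adjusted p = 4.415e-08). DUSP6 lay above DPBS with BAPTA-AM and EGTA, by 0.96 ± 0.08 and 0.79 ± 0.08 in H1437-3 and by 3.85 ± 0.12 (82.2 ± 3.69 against 5.71 ± 0.452 CPM, adjusted p = 1.132e-14) and 2.63 ± 0.12 in H292-2. So did the ERK feedback and output genes as a list, 6 of 13 with 1 lower (2 lower adjusted over the list alone, median 0.12, adjusted p = 0.02918) and 9 (11 adjusted over the list alone, 0.34, adjusted p = 0.001625) in H1437-3, and 11 (1.13, adjusted p = 0.007263) and 12 (1.11, adjusted p = 0.004379) in H292-2. This was not particular to the ERK list. NF-kB feedback genes had medians of 0.83 and 0.72 in H1437-3, and 0.51 and 1.26 in H292-2. Chemokines had 2.54 and 3.26, and 2.31 and 3.11. The adjusted p of these lists ran from 0.001571 to 0.02139 with an estimated correlation. Immediate early genes and the calcium, CREB and NFAT targets passed above DPBS with EGTA in both experiments, but not with BAPTA-AM. With EGTA the Aeg-S/L set stood above DPBS by a median of 0.78 in H1437-3 (0.31 and 1.49, 143 of 200 genes, adjusted p = 0.0008518 with an estimated correlation) and 0.82 in H292-2 (0.33 and 1.58, 148 of 198 with 13 lower, adjusted p = 0.001192). With BAPTA-AM it stood at 0.28 (0.27 with bounds, 95 of 200 higher and 39 lower) and 0.17 (85 of 198 higher and 63 lower), both with adjusted p = 0.07122 with an estimated correlation.

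Extracts labelled aegs KO and aegl KO were set against the WT extract in both lines. In H1437-4 FOS was lower by 7.43 ± 0.17 with aegs KO (adjusted p = 1.149e-14) and 7.46 ± 0.17 with aegl KO (adjusted p = 9.966e-15), and in H292-1 by 9.61 ± 0.21 (adjusted p = 1.37e-09) and 8.76 ± 0.2 (adjusted p = 2.448e-09). CXCL8 was lower by 8.17 ± 0.2 and 7.72 ± 0.19 in H1437-4 and by 7.61 ± 0.25 and 7.78 ± 0.25 in H292-1. IL6 had 0 counts with aegs KO in H1437-4, at least 2729-fold lower than with the WT extract (adjusted p = 1.514e-12), and was lower by 10.04 ± 0.28 with aegl KO. BMF was higher by 1.99 ± 0.22 with aegs KO and 2.1 ± 0.22 with aegl KO in H1437-4, and by 3.87 ± 0.27 and 2.69 ± 0.27 in H292-1. HMOX1 was higher by 5.08 ± 0.22 with aegs KO (adjusted p = 1.258e-07) and 4.54 ± 0.22 with aegl KO in H292-1 (adjusted p = 3.675e-07). Immediate early genes were lower, 19 of 20 with either extract in H1437-4 (medians −3.82 and −3.75, 20 with aegs KO adjusted over the list alone) and 18 of 20 with 1 higher in H292-1 (−4.31 and −4.34, 19 with aegs KO adjusted over the list alone). NRF2 targets were higher in H292-1, 7 of 9 with aegs KO (8 adjusted over the list alone, median 1.42, adjusted p = 0.005273) and 8 of 9 with aegl KO (1.29, adjusted p = 0.003488). The ALT set of H1437-1 fell by 1.83 (−3.03 and −0.97, 189 of 200 genes, adjusted p = 0.0002066 with an estimated correlation) and 1.73 (−2.86 and −1, 185, adjusted p = 0.0001684) in H1437-4, and by 0.94 (−2.73 and −0.17, 113 of 185, adjusted p = 0.0001473) and 0.73 (−2.65 and −0.06, 98, adjusted p = 0.0001473) in H292-1.

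Against DPBS little was left of the response of FOS and the ALT set, whereas some genes kept a part of theirs, such as DUSP6 with aegl KO in H292-1. FOS did not pass with aegs KO (−0.23, adjusted p = 0.6895) or aegl KO (−0.26, adjusted p = 0.5982) in H1437-4, and the ALT set had medians of 0.02 (0.01 with bounds, adjusted p = 0.5394) and 0.1 (adjusted p = 0.09143). In H292-1 the medians were −0.03 (adjusted p = 0.2763) and 0.16 (adjusted p = 0.007558). Of 200 genes of the set, 4 were higher with aegs KO, and 10 with 1 lower with aegl KO, in H1437-4. Of 185 tested, 0 and 7 were higher in H292-1. There DUSP6 remained 2.55 ± 0.15 higher with aegl KO than with DPBS (34.9 ± 0.143 against 5.97 ± 1.20 CPM, adjusted p = 9.29e-05) and SPRY4 2.69 ± 0.21 higher (adjusted p = 0.0004561). With aegs KO neither passed, at 0.3 and 0.27 (adjusted p = 0.9997 for both). ERK feedback and output genes rose as a list with aegl KO against DPBS, 7 of 13 (11 adjusted over the list alone, median 1.02, adjusted p = 0.03412 with an estimated correlation). BMF lay below DPBS with aegl KO in H292-1 by 1.49 ± 0.23 (adjusted p = 0.04959), which did not pass when any 1 of the 4 libraries was left out (adjusted p = 0.08376 to 0.4483). With aegs KO in H1437-4 it lay 0.83 ± 0.19 below (adjusted p = 0.04258), not passing with the replicate number as a block (adjusted p = 0.06294) or when any 1 of the 4 libraries was left out (adjusted p = 0.1427 to 0.4262). With aegl KO in H1437-4 (−0.72, adjusted p = 0.08183) and aegs KO in H292-1 (−0.32, adjusted p = 0.9997) it did not pass. The difference between the 2 knockout extracts was not tested. Over all genes of H1437-4, 2625 were higher and 2377 lower with aegs KO than with the WT extract, and 2699 and 2421 with aegl KO. The totals of 5002 and 5120 became 3212 without aegs KO 1, 3226 without aegs KO 2, 3096 without aegl KO 1 and 3212 without aegl KO 2. In H292-1 they were 2186 and 2227, and 1637 and 1516. The total of 4413 became 1703 without WT ALT 1, 1838 without WT ALT 2 and 2698 without aegs KO 1, and that of 3153 became 1122 without WT ALT 1, 1172 without WT ALT 2 and 1941 without aegl KO 1.

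**Figure D3:**
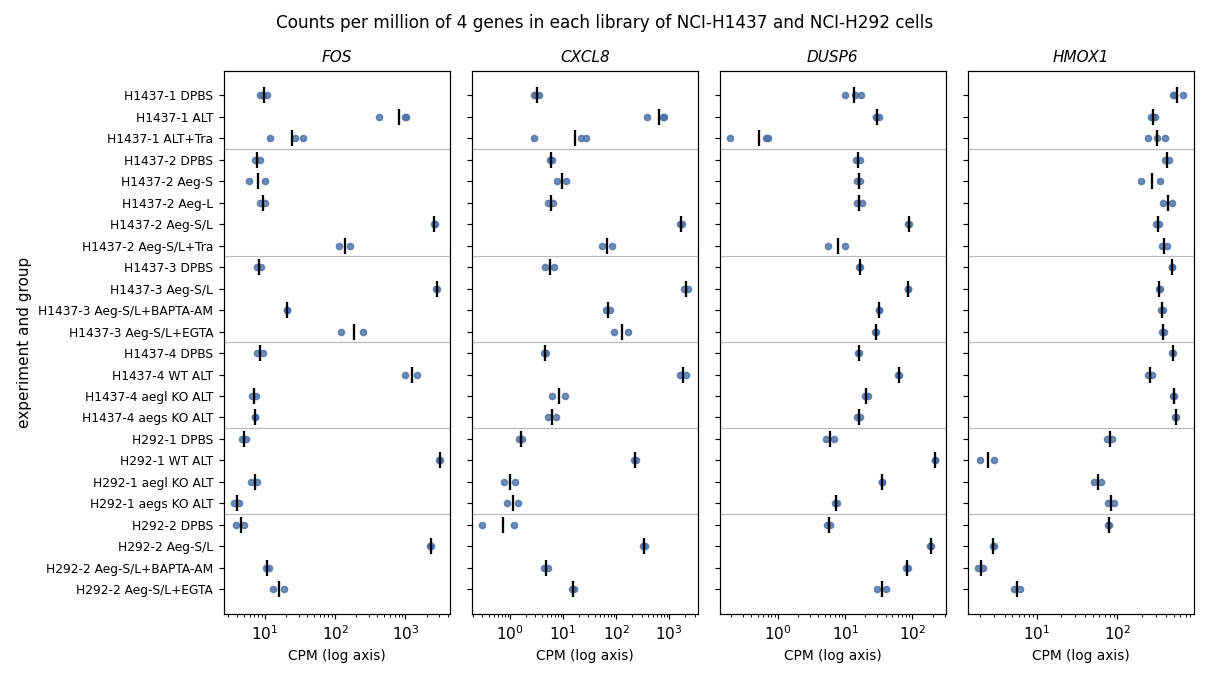
CPM on a log axis of FOS, CXCL8, DUSP6 and HMOX1 in each library of the 6 human experiments, by experiment and group. Points are libraries and black bars group means, such as 3067 CPM of FOS under the WT extract and 7.06 CPM with aegl KO in H292-1.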

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

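The random lists matched on expression and the 3 counts from other splits of libraries were written down before the results were seen, and every other test here was chosen after. Most of the results were picked out because an effect differed between experiments of different mice or cell lines. The mitochondrial share and the splits concern comparisons within an experiment. No experiment held 2 genotypes or 2 lines, so none of the differences between mice or lines can be told apart from one between experiments.

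The response to ALT differed between IL33KO1 and Lung1 in 2725 genes, and became 4686 without DPBS 2 of IL33KO1 and 1636 with the replicate number as a block. That to Aeg-S/L differed between IL33KO1 and Lung2 in 1733 genes. Without 1 library this became 4106 (IL33KO1 DPBS 2), 303 and 326 (IL33KO1 Aeg-S/L 1 and 2), 300 and 526 (Lung2 Aeg-S/L 1 and 2), or 738 and 568 (Lung2 DPBS 1 and 2). With DESeq2 it was 2967, without the low-count filter 3092 and with the block 838. Between Rag2gc and Lung2 it differed in 1491 genes, which became 666 and 778 (Lung2 Aeg-S/L 1 and 2), 711 (Lung2 DPBS 2), 541 and 792 (either Rag2gc DPBS library), or 569 and 600 (Rag2gc Aeg-S/L 1 and 2). With DESeq2 it was 2295 and without the filter 2812.

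Between IL33KO2 and Lung4 the response to lysenin differed in 2843 genes. Leaving out 1 library gave 5235 and 6780 (IL33KO2 DPBS 1 and 2), 1560 and 1620 (either IL33KO2 Lysenin library), 1613 (Lung4 DPBS 1), or 1533 and 1539 (Lung4 Lysenin 1 and 2). The response to PlyA2EryB differed in 2872, with 5219 and 7179 (IL33KO2 DPBS 1 and 2), 1553 and 1793 (either IL33KO2 PlyA2EryB library), 1663 (Lung4 DPBS 1), or 1684 and 1627 (Lung4 PlyA2EryB 1 and 2). That to LSL differed in 4422 genes, or 7512 without IL33KO2 DPBS 2.

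Between the cell lines, H292-2 and H1437-3 differed in 2662 genes in their response to Aeg-S/L, and H292-1 and H1437-4 in 1656 in their response to ALT. The latter became 1031 without H1437-4 WT ALT 2, 922 and 951 without H1437-4 DPBS 1 and 2, 1036 without H292-1 DPBS 1, and 841 and 894 without H292-1 WT ALT 1 and 2. In NCI-H292 the ERK feedback and output genes rose further, 9 of 13 under Aeg-S/L with 1 lower (10 adjusted over the list alone, median 0.85, adjusted p = 0.0004968) and 7 under ALT (0.81, adjusted p = 0.02088). NF-kB feedback genes rose less, 8 lower under Aeg-S/L (9 adjusted over the list alone, −0.75, adjusted p = 0.001107) and 10 lower with 1 higher under ALT (−1.1, adjusted p = 0.01341).

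NRF2 targets such as HMOX1 fell further in NCI-H292 than in NCI-H1437 under Aeg-S/L, 9 of 9 with a median difference of −0.79 (adjusted p = 9.105e-06 with an estimated correlation). Scaling itself puts the median of all genes at 0, so that median cannot test an error in the scaling of the libraries. Such an error would shift all genes of a library by a common factor, random lists included. Among 10000 random lists matched on expression in 20 bins, the 1st percentile was −0.17 and the lowest median −0.75. This puts the list at percentile 0. The genes of each random list were drawn independently, so the lists do not reflect shared regulation of the 9 targets, and the percentile is no p-value. The other pair of experiments, under ALT, gave −1.32 with 8 of 9 lower (adjusted p = 0.0006388). The random lists argue against scaling and against the expression level of the genes as the cause, and the ALT values against 1 odd pair of experiments.

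Mitochondrial transcripts took 0.2 ± 0.02% of counts in the BAPTA-AM libraries of H292-2. Library depth could set such a share, but among 28 human libraries at least as deep and without BAPTA-AM the lowest share was 0.99%. The lowest of all human libraries without BAPTA-AM was 0.55%, in the shallower H292-1 aegl KO 1. Dilution by a few other transcripts would lower most nuclear genes and mitochondrial genes alike. Yet 16 of 16 mitochondrial genes fell, with a median of −3.63, against −0.08 (−0.29 and 0.1) for 2282 nuclear genes of at least 100 CPM, a difference of −3.56 that scaling does not change. Both values argue against the explanation they tested, the second for dilution by a few transcripts only. A rise of most nuclear transcripts would give the same difference, since scaling sets their level, so it cannot be told apart here.

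The ALT response was smaller in IL33KO1 than in Lung1. Spread between replicates that differs from gene to gene could hide calls without moving medians. The Aeg-S/L set of Lung2 had a median difference of −0.96 (−1.61 and −0.47, 93 of 200 genes lower and 2 higher, p = 0.001128 by camera with an estimated correlation), which argues against such spread alone. A deviation of a library that the genes of the set share could still move the median. The IL33KO1 controls were unlike each other, with 5.83% mitochondrial counts in DPBS 1, which stands apart, and 3.06% in DPBS 2. The median was −0.89 without the former and −0.85 without the latter, and lay between −1.22 and −0.85 over all libraries left out in turn. Experiments that held both genotypes numbered 0, so genotype and experiment cannot be told apart.

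Splits of the 6 libraries into other groups, 10 for each comparison including the real one, are too few for a share under 0.05. The real split called 10433 genes in Lung1, 766 for ALT and 826 for Tra in H1437-1, the highest other split called 0, and 1 split in each called as many as the real one.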

How the results depend on the processing

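The medians of the response sets with inhibitors, chelators and knockout extracts against the stimulus (12 results) kept their direction, and an unadjusted p under 0.05 by camera, in 98 of 98 alternatives. Their size grew with at most 100 genes per set, to −2.7 and −2.54 in Lung3, −2.1 and −1.77 with Tra, −2.93 and −2.19 with BAPTA-AM and EGTA in H1437-3, −2.49 and −1.98 in H292-2, −2.27 and −2.12 with aegs KO and aegl KO in H1437-4, and −1.15 and −1.03 in H292-1. Except in the setting with an estimated correlation, these p values used the preset correlation, with which the main ones were at most 6.249e-79 by camera. A call could then hardly be lost, so these alternatives do not test it. Calls with an estimated correlation were not recomputed under the other settings. The rises of the sets under the stimuli were not recomputed. Counts of called genes moved by over 1.5 times in many. Groups of 2 libraries leave few degrees of freedom, and the cause of each move was not tested. DESeq2 moved 12 of 49 counts: Aeg-S 13 and Aeg-L 10 in Lung2, ALT 2465 and Aeg-S/L 4300 in IL33KO1, ALT 1394 and Tra 1593 in H1437-1, Aeg-S 3, Aeg-S/L 1931, Tra 424 and the difference from the sum 1420 in H1437-2, and the differences of IL33KO1 (2967) and Rag2gc (2295) from Lung2 under Aeg-S/L. Without the low-count filter 13 moved: 775 and 132 in Lung2, 2803 and 4648 in IL33KO1, 1153 and 1864 in H1437-1, 278, 9 (Aeg-L), 2143, 447 and 1913 in H1437-2, and 3092 and 2812 for the differences. DESeq2 size factors moved 0 of 49. The replicate number as a block moved 4 of 43: 266 for ALT and 1074 for Aeg-S/L in IL33KO1, and 838 and 1636 for the differences of these from Lung2 and Lung1. Whether samples with the same number deviate together was measured where groups held 3 libraries, over 1000 genes. In Lung1 r was 0.24, 0.09 and 0.31, and in H1437-1 it was 0.66, 0.3 and 0.62 between DPBS and ALT+Tra but −0.63 to 0.32 between ALT and the others, so it was not over 0.1 in every pair. A library correlated best with its own number in 5 of 6 cases in Lung1 and 10 of 18 in H1437-1, and the numbers were taken as labels only. The block was not run where columns carry no number (IL33KO2 lysenin and PlyA2EryB, Rag2gc, and their differences). Of 192 list calls with the preset correlation, among 320 tests in 20 human comparisons, 124 held with an estimated correlation. This tally leaves out inhibitors, chelators and knockout extracts against DPBS, differences from the sum and differences between lines. The median correlation of fold changes over 106 pairs of comparisons was 0.53, and 0.69 for genes of at least 10 CPM. These pairs mix stimuli, mice and cell lines and include Aeg-S and Aeg-L alone, so the median does not measure how well a response repeats. For ALT in Lung1, r was 0.04 with Aeg-S and 0.86 with Aeg-S/L in Lung2, and 0.87 with WT ALT in Lung3. Between ALT in H1437-1 and WT ALT in H1437-4 it was 0.56.

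Without libraries that stand apart, chosen after the data were seen, 7 of 13 counts moved: 1 for Aeg-L in Lung2, 9265 for aegs KO and 9071 for aegl KO in Lung3, 2076 for ALT in IL33KO1, 2812 for ALT and 2773 for Tra in H1437-1, and 1881 for Aeg-S/L in H1437-2.

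Without each library of the compared groups in turn, counts ranged as follows. Libraries of other groups in the same fit were not left out for these ranges. Fits without libraries that stand apart, given above, moved some counts beyond them. Lung1 ALT 9413 to 9957; Lung2 Aeg-S 0 to 1329, Aeg-S/L 4246 to 5150, difference from the sum 1897 to 5790; Lung3 WT ALT 3228 to 10266, aegs KO 2297 to 2648, aegl KO 2209 to 2396. Lung4 lysenin 10539 to 11609, PlyA2EryB 10916 to 11781, LSL 10852 to 12051, PlyA2EryB against lysenin 2332 to 2646, LSL against lysenin 3160 to 3430, LSL against PlyA2EryB 4135 to 4538. IL33KO1 ALT 25 to 2820, Aeg-S/L 222 to 6204, IL33KO2 lysenin 4206 to 11604, PlyA2EryB 6293 to 12758, LSL 3526 to 11510, Rag2gc 10824 to 12173. H1437-1 ALT 294 to 1129, Tra 278 to 941, H1437-2 Aeg-S 0 to 1544, Aeg-L 0 to 1, Aeg-S/L 269 to 337, Tra 80 to 98, difference from the sum 148 to 4373. H1437-3 Aeg-S/L 3555 to 4553, BAPTA-AM 3210 to 4008, EGTA 3399 to 3521, between them 4774 to 5540. H1437-4 WT ALT 3773 to 5813, aegs KO 3212 to 5701, aegl KO 3096 to 5707. H292-1 WT ALT 1481 to 2519, aegs KO 1703 to 4950, aegl KO 1122 to 2659. H292-2 Aeg-S/L 5321 to 5602, BAPTA-AM 4642 to 4674, EGTA 5710 to 7367, between them 5945 to 7594. Differences from mice of other experiments, ALT 1824 to 4686, Aeg-S/L 300 to 4106 (IL33KO1) and 541 to 1413 (Rag2gc), lysenin 1533 to 6780, PlyA2EryB 1553 to 7179, LSL 3019 to 7512. Between lines, Aeg-S/L 1897 to 2249 and ALT 841 to 1436.

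Of 2456 alternatives for 297 values of 38 named genes, 2371 kept the call, 51 lost it, 22 gained it and 12 turned in direction. The turned ones, with the values farthest on the other side, were IL6 between the chelators in H292-2 (−0.04 without EGTA 2, −0.34 without BAPTA-AM 2, 0.32 without BAPTA-AM 1), CXCL2 between them in H1437-3 (−0.04 without BAPTA-AM 2, −0.15 without EGTA 2, 0.37 without EGTA 1), EGR1 in H292-2 (0.17 without EGTA 1, −0.79 without EGTA 2), DUSP6 with aegs KO against DPBS in H1437-4 (−0.06 without aegs KO 1, −0.01 without DPBS 2), BMF in H1437-3 with BAPTA-AM against Aeg-S/L (0.05 without Aeg-S/L 2, −2.32 without BAPTA-AM 2) and with EGTA against DPBS (0.12 without EGTA 1, −0.74 without EGTA 2), and IL33 under Aeg-S/L in H1437-2 (0.29 without Aeg-S/L 1, −0.98 without Aeg-S/L 2) and under WT ALT in H1437-4 (0.08 without WT ALT 2, 0.54 without DPBS 2, −0.58 without DPBS 1).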

Other observations

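Cell cycle genes fell under stimulation in NCI-H292 cells: 7 of 11 under ALT in H292-1 (9 adjusted over the list alone, median −0.81, adjusted p = 0.01492) and 11 of 11 under Aeg-S/L in H292-2 (−0.7, adjusted p = 0.01439). MKI67, a mark of dividing cells, fell by 1.53 ± 0.06 and TOP2A, which untangles DNA, by 0.88 ± 0.05 in H292-2 (adjusted p = 9.119e-11). In H1437-3 7 of 11 fell (−0.24, adjusted p = 0.04546), with TOP2A lower by 0.79 ± 0.06. In H1437-4 8 fell (9 adjusted over the list alone, −0.31) and in H1437-2 2 fell (3 adjusted over the list alone, −0.32), with adjusted p = 0.2267 and adjusted p = 0.1483 with an estimated correlation. In H1437-1 1 fell (−0.12, adjusted p = 0.4596). With the chelators the list rose in H292-2, 10 of 11 with BAPTA-AM (0.65, adjusted p = 0.03938) and 9 with EGTA (10 adjusted over the list alone, 0.6, adjusted p = 0.02247).

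Cholesterol synthesis genes fell in the same line, 7 of 12 with 1 higher in H292-1 (median −0.69, adjusted p = 0.01887) and 10 of 12 with 1 higher in H292-2 (−0.51, adjusted p = 0.03446). SQLE fell by 0.78 ± 0.12 in H292-1 (adjusted p = 0.001037) and 0.81 ± 0.07 in H292-2 (adjusted p = 1.924e-08). In NCI-H1437, 8 of 12 fell with 1 higher in H1437-4 (−0.28) and 7 with 2 higher in H1437-3 (−0.21), with adjusted p = 0.2583 and adjusted p = 0.1856 with an estimated correlation. H1437-2 had 3 lower (−0.23, adjusted p = 0.1483, 4 with 1 higher adjusted over the list alone) and H1437-1 0 (0.09, adjusted p = 0.8472). With the knockout extracts the list was higher than with the WT extract in H292-1, 7 of 12 for aegs KO (8 with 1 lower adjusted over the list alone, 0.91, adjusted p = 0.01209) and 10 for aegl KO (1, adjusted p = 0.005679).

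Among EGF receptor ligands, HBEGF rose by 2.51 ± 0.28, 2.64 ± 0.15, 2.92 ± 0.25 and 3.44 ± 0.13 in H1437-1, H1437-4, H1437-2 and H1437-3, and by 4.5 ± 0.18 and 5.08 ± 0.08 in H292-1 and H292-2. The ligand list rose in H1437-2 (3 of 7, median 0.41, adjusted p = 0.04944), H1437-3 (4 of 7 with 1 lower, 1.35, adjusted p = 0.02358), H1437-4 (4 of 8 with 1 lower, 1.29, adjusted p = 0.01915, 5 higher adjusted over the list alone) and H292-2 (4 of 8 with 1 lower, 0.46, adjusted p = 0.01439). In H1437-1 3 of 7 rose (0.49) and in H292-1 3 of 8 with 1 lower (0.58), with adjusted p = 0.0584 and adjusted p = 0.05003 with an estimated correlation.

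Integrated stress response genes rose in H1437-2 (4 of 11, median 0.51, adjusted p = 0.04944, 5 adjusted over the list alone), H1437-3 (6, 0.2, adjusted p = 0.007701) and H1437-4 (6 with 1 lower, 0.31, adjusted p = 0.01219), where DDIT3, a factor of this response, rose by 3.02 ± 0.57, 3 ± 0.15 and 2 ± 0.22. In H1437-1 and H292-1 the list medians were −0.09 and −0.01 (adjusted p = 0.8472 and adjusted p = 0.5155), and in H292-2 0.11, with adjusted p = 0.3166 with an estimated correlation. Heat shock genes rose in 9 of 9 cases in H292-2 (0.33), 5 of 9 in H292-1 (0.46) and 1 of 9 in H1437-1 (3 adjusted over the list alone, 0.44), with adjusted p = 0.06409, adjusted p = 0.1786 and adjusted p = 0.0771 with an estimated correlation. Their medians were 0.08, 0.22 and −0.05 in H1437-2, H1437-3 and H1437-4. ER chaperones fell in 7 of 11 cases with 1 higher in H292-2 (−0.26, adjusted p = 0.2744 with an estimated correlation), and in the other 5 experiments the medians lay between −0.09 and 0.01.

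Annexins and membrane repair genes rose in 8 of 15 cases in H1437-4 (median 0.25, adjusted p = 0.3069 with an estimated correlation) and 7 of 15 in H1437-3 (0.17, adjusted p = 0.592). The list medians were 0.04, 0.17, −0.13 and 0.02 in H1437-1, H1437-2, H292-1 and H292-2. Interferon-stimulated genes gave no call as a list, with medians of −0.26, −0.22, −0.22, −0.18, −0.26 and −0.4 in H1437-1, H1437-4, H1437-2, H1437-3, H292-1 and H292-2. Mucus and goblet genes gave medians of 0.22, 0.27, 0.4, 0.22, −0.03 and −0.36 in the same order. In H1437-2 2 of 9 rose (3 adjusted over the list alone), with adjusted p = 0.1124 with an estimated correlation. In H1437-3 4 of 9 rose (adjusted p = 0.4965), in H1437-4 2 (adjusted p = 0.8082) and in H1437-1 1 (adjusted p = 0.4568). Of 7 tested in NCI-H292, 1 rose and 2 fell in H292-1 (adjusted p = 0.8656), and 1 fell in H292-2 (adjusted p = 0.613).

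Mitochondrial transcripts took 2.25 ± 0.23% of counts in DPBS of H292-2 and 2.18 ± 0.28% in DPBS of H1437-3. In H292-1 they took 2.65 ± 0.2% in DPBS, 1.0 ± 0.02% under the WT extract, 2.42 ± 0.26% with aegs KO and 1.4 ± 1.21% with aegl KO. Standard errors, intervals and floors cover the spread between the libraries at hand and counting error only.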
